A study of Danio rerio with 6 samples.

How the data were processed

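The data were Smart-seq2 libraries, a full-length cDNA method that carries no molecular identifiers, made from zebrafish larval kidney blood cells. Per the labels' protocols, larvae of the transgenic line Tg(coro1a:DenNTR), in which the leukocyte promoter coro1a drives the photoconvertible protein Dendra2 joined to NTR, were treated with DMSO or MTZ. With NTR transgenes, MTZ is usually metronidazole, which nitroreductase turns into a cell toxin. At 3.5 dpt (9 dpf) the kidney region was irradiated with a 405-nm laser for 30 s, which turned its labelled cells red, about 80 larvae were pooled and dissociated, and 50 red cells were sorted into each library. There were 3 libraries per group. The labels do not state that the libraries of a group came from separate pools of larvae, so p-values measure only the spread between these libraries, which may be technical.

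The authors deposited 1 table of estimated counts per gene, which were not scaled to a common total. Per the submitters' processing notes, HISAT2 and the GRCz11 build were used. Their versions, the counting tool, the annotation release and the use of strand are not given in the sources used here. The unit was read from the values: between 8.31% and 9.90% of the nonzero values of a library had decimals, so they were read as estimated (expected) counts and rounded to whole numbers. The table held 27314 rows, of which 25116 had an Ensembl gene ID and 2198 an ID starting with MSTRG, a form that transcript assemblers give to loci. The 1913 rows without a symbol had IDs and stayed in the library totals and in the test, and they took between 1.60% and 5.21% of a library's counts. There were 9403 rows at 0 in all 6 libraries. Symbols came from the deposited table. No coordinates are printed, because no annotation of GRCz11 was used here. Genes with close copies (ribosomal proteins, hemoglobins, histones, chemokines and immune families) and overlapping or antisense genes are uncertain, since the counting could have split or merged their reads.

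Total counts were 14058382, 16400587 and 14910020 in the DMSO libraries and 18610390, 16928977 and 20674280 in the MTZ libraries. A count of 3 corresponded to between 0.149 and 0.233 CPM (counts scaled by the TMM-adjusted library size). Intervals and floors cover counting error only, because reads without molecular identifiers are not independent molecules.

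The comparison of MTZ with DMSO used the quasi-likelihood test of edgeR 4.0.16 on R 4.3.3 (two-sided), with TMM factors, the default expression filter (minimum count of 10) and a model with the group alone. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over the 10283 genes tested, 750 of them MSTRG loci. Standard errors of log2 fold changes were computed as the size of the fold change divided by the square root of the test's F. Means are given with the SD over the 3 libraries of a group, in CPM. For 40 gene lists fixed before the data were examined (20 of cell type markers, including cell types outside the sort, and 20 of pathways), camera in limma 3.58.1 was run with a preset inter-gene correlation of 0.01. The 33 lists with at least 3 tested members formed 1 Benjamini-Hochberg family. Of 1047 list entries written by name, 41 had no match in the table and 17 symbols were matched through a table of gene IDs. Member p-values were also adjusted over the list alone, which makes no allowance for the number of lists, so some members can pass by chance. Library composition was compared by a two-sided exact permutation test over 20 relabellings, which cannot give a p below 0.1.

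Named genes followed a rule fixed before the data were examined. It took the 8 higher and 8 lower genes of smallest p among those past the threshold, or 4 per direction where fewer than 4 passed, passing over clone names (3 among the lower genes), 12 genes given in advance, and the 4 leading members of each called list. This gave 24 genes, 21 of them tested. Other list members named in the text were chosen after their values were seen. The alternatives were run on the 21 tested genes of the rule, on the 4 members of smallest p in each list with a camera p under 0.1 and in the CXCR4 list, and on cdc42 and cfl1. For a gene at 0 in every library of a group, the fold is a lower bound against 3 counts over the group. For a gene with 1 to 3 counts in a group, the ratio of the pooled rates is given with an exact 95% counting interval.

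Alternatives fixed in advance were DESeq2 1.42.0, limma voom with and without sample quality weights, other scaling factors, no filter and a filter of 10 CPM in 3 libraries, the replicate number as a block, robust dispersion, thinned counts, and leaving out each library. Lists were also tested with an estimated correlation, with fry, and without members of more than 1 list. The test was checked on simulated counts for MTZ against DMSO with 200 changed genes. With a dispersion of 0.05 for every gene (10265 genes in the step), 66 of 67 genes changed 4-fold were recovered. With the dispersion of the real libraries (9263 genes in the step), edgeR recovered 4 of 57 tested genes changed 4-fold. It recovered 14 of 59 changed 16-fold and 34 of 61 changed 64-fold. False calls by edgeR numbered 6 at the real dispersion and 7 at a dispersion of 0.05. A simulated list shifted 2-fold, with genes drawn independently of each other, had an unadjusted camera p of 0.00489 at the real dispersion. Genes of a real list can move together, so this does not show that such a shift would pass in a real list.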

Results

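The series profiled coro1a-labelled blood cells from the larval zebrafish kidney, the organ that holds blood stem and progenitor cells in fish, after MTZ or DMSO. Its title concerns the CXCR4-CXCL12 chemokine axis and the renewal of T cells by immigrating stem and progenitor cells. The single comparison its labels give is MTZ against DMSO. Each group had 3 libraries of 50 cells, with between 14058382 and 20674280 counts per library. Mean values below carry the SD over the 3 libraries of a group, in CPM (counts scaled by library size), and log2 fold changes carry their standard error.

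The kidney cells of both groups expressed the chemokine receptor genes cxcr4b and ccr9a strongly. The receptor gene cxcr4b (ENSDARG00000041959) had 2970 ± 335 CPM in MTZ and 1946 ± 724 CPM in DMSO, a log2 fold change of 0.61 ± 0.27 that did not pass the test (edgeR adjusted p = 0.9997). Its paralog cxcr4a (ENSDARG00000057633) was detected at 106 CPM in MTZ 2 and 10.1 CPM in MTZ 3, and it had 3 counts in all DMSO libraries together and none in MTZ 1. Too few libraries held it for testing. The ratio of its pooled MTZ and DMSO rates was 526, with a counting interval from 180 to 2552 that ignores the spread between libraries.

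Among the ligands, cxcl12a (ENSDARG00000037116) had 40.2 ± 35.4 CPM in MTZ and 6.69 ± 5.80 CPM in DMSO, with 1 library of each group at 1 count or 0. The ligand gene cxcl12b (ENSDARG00000055100) was seen in DMSO 3 alone, at 14.8 CPM. The decoy receptor gene ackr3b (ENSDARG00000058179) was seen almost entirely in MTZ 2, at 84.6 CPM. Of the thymus-homing receptors, ccr9a (ENSDARG00000055186) had 1773 ± 1033 CPM in MTZ against 1572 ± 396 in DMSO. Its paralog ccr9b (ENSDARG00000099738) had 116 ± 78.3 against 218 ± 122. The fixed list of this axis and of thymus homing had 6 tested members, 5 higher and 1 lower in MTZ, with a median log2 fold change of 0.74. No member passed over all genes or when adjusted over the list alone, and the list did not pass as a group (camera adjusted p = 0.418).

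**Figure D1:**
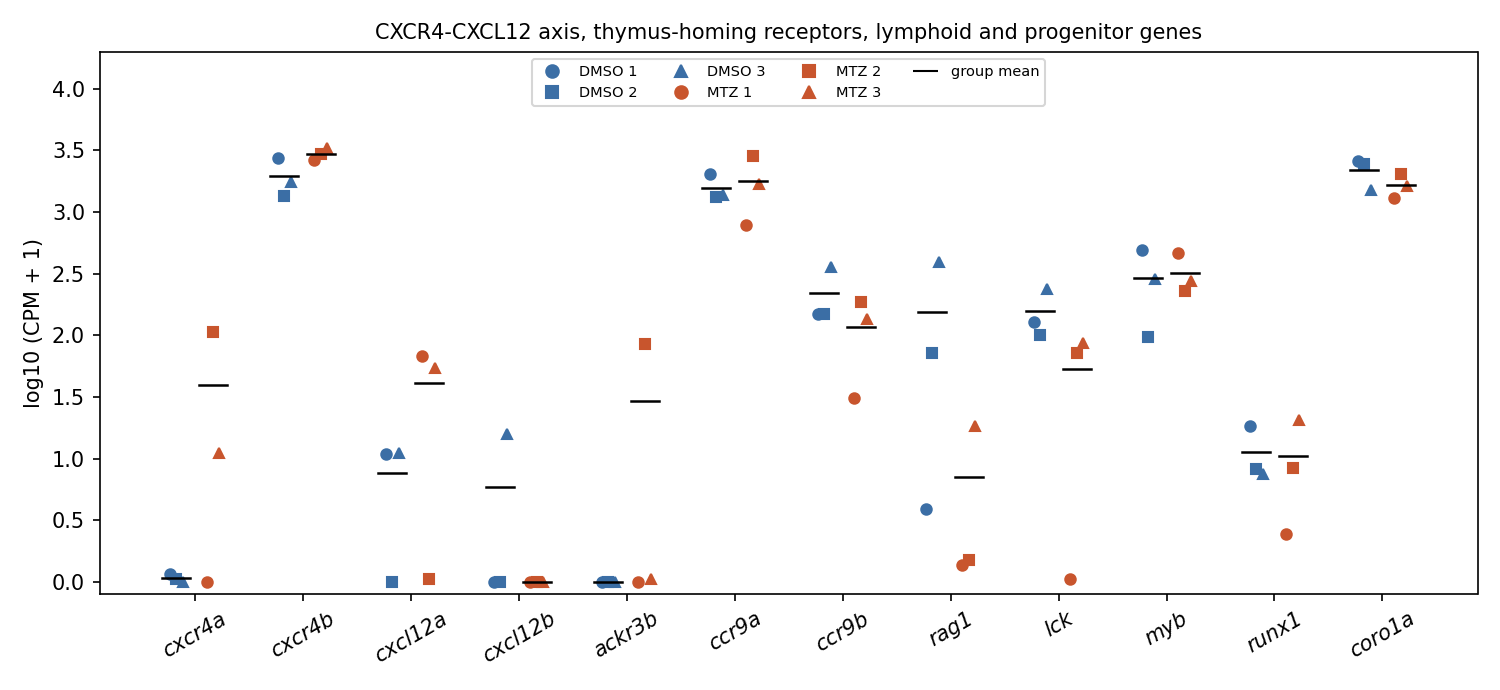
Expression of 12 genes fixed in advance, as log10 of CPM plus 1, in each of the 3 DMSO (blue) and 3 MTZ (orange) libraries, with a bar at the mean CPM of each group. The cxcr4b points of MTZ lie between 2647 and 3316 CPM and those of DMSO between 1350 and 2752 CPM, and rag1 and lck vary widely between libraries of one group.

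The lymphocyte genes rag1, rag2 and lck had lower means in MTZ, and for rag1 and rag2 the libraries of the groups overlapped. The fixed lymphoid progenitor list was split between higher and lower members (given below), and its ikzf1 had 233 ± 64.2 CPM in MTZ and 166 ± 41.7 in DMSO. The recombinase gene rag1 (ENSDARG00000052122), which cuts antigen receptor genes, had 2.88, 71.2 and 390 CPM in the DMSO libraries and 0.378, 0.495 and 17.5 CPM in the MTZ libraries (log2 fold change -4.66 ± 1.97). Its partner rag2 had 181 ± 182 CPM in DMSO and 18.96 ± 19.9 in MTZ. The T cell kinase gene lck (ENSDARG00000102525) had 155 ± 73.4 against 52.3 ± 45.9. The progenitor transcription factor genes myb (ENSDARG00000053666) and runx1 (ENSDARG00000087646) had similar means. They stood at 321 ± 127 CPM in MTZ against 291 ± 198 in DMSO for myb and at 9.50 ± 9.25 against 10.4 ± 6.15 for runx1. The transgene's promoter gene coro1a (ENSDARG00000054610) had 1637 ± 363 CPM in MTZ and 2180 ± 585 in DMSO. None of these differences passed edgeR's test (adjusted p = 0.9997 for each). EdgeR without a filter on low counts called rag1 and rag2 (adjusted p = 0.00439 and 0.0338), and DESeq2 called neither (0.1703 and 0.4904). With a library left out, the log2 fold change ran from -8.43 to -2.59 for rag1, from -4.39 to -2.10 for rag2 and from -2.12 to -0.97 for lck. It ran from 0.41 to 0.96 for cxcr4b, from 2.01 to 3.18 for cxcl12a, from -1.40 to -0.35 for ccr9b and from -0.62 to -0.26 for coro1a. Leaving out MTZ 2 turned ccr9a to -0.33, leaving out DMSO 2 or MTZ 1 turned myb to -0.27 or -0.21, and leaving out DMSO 1, MTZ 1 or MTZ 2 turned runx1 to 0.48, 0.39 or 0.03.

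Across all genes, the higher genes of smallest p in MTZ were vps52, junbb, cndp2 and rbp4. The AP-1 transcription factor gene junbb (ENSDARG00000104773) had 442 ± 115 CPM in MTZ and 102 ± 54.8 in DMSO (log2 fold change 2.12 ± 0.44). The peptidase gene cndp2 (ENSDARG00000003931) had 194 ± 75.8 against 39.1 ± 11.7. The retinol carrier gene rbp4 (ENSDARG00000101199) had 473 ± 221 against 34.3 ± 35.6. The gene vps52 (ENSDARG00000099258), for a subunit of a vesicle tethering complex, had no counts in DMSO and 54.4 ± 23.3 CPM in MTZ. Over a floor of 3 counts in the group it was at least 825.5-fold higher. That bound covers counting error only and ignores the spread between libraries.

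The lower genes of smallest p, with 3 clone-named genes passed over, were arpp21, ercc6, gnptab and ccl34b.1. The gene arpp21 (ENSDARG00000061081) had 46.4 ± 34.2 CPM in DMSO and 3 counts in all MTZ libraries, a ratio of 807 with a counting interval from 276 to 3916. The DNA repair gene ercc6 (ENSDARG00000075612) had 35.9 ± 20.6 CPM and 2 counts, a ratio of 932 with an interval from 258 to 7700. Both intervals ignore the spread between libraries. The gene gnptab (ENSDARG00000030153), for an enzyme that tags lysosomal proteins, had 51.9 ± 36.4 CPM in DMSO and 0.235 ± 0.311 in MTZ. The chemokine gene ccl34b.1 (ENSDARG00000093608) had 314 ± 283 CPM in DMSO and 2.61 ± 3.95 in MTZ.

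None of these 8 genes passed edgeR's test, which called 0 of 10283 genes with a smallest adjusted p of 0.9997. DESeq2 called all 8, with adjusted p-values from 1.22e-08 for vps52 to 0.00294 for cndp2. EdgeR without a filter on low counts called vps52, junbb, rbp4 and ccl34b.1. The unfiltered run was not checked on simulated counts or on other splits of the libraries, so its share of false calls is not known. With a library left out, the log2 fold change ran from 3.33 to 5.08 for rbp4, from -10.46 to -8.75 for arpp21, from -9.67 to -7.11 for gnptab and from -9.84 to -6.16 for ccl34b.1. At an unadjusted p under 0.05 there were 327 genes (188 higher and 139 lower in MTZ), where evenly spread p-values would give 514. The 9 other splits of the 6 libraries into 3 and 3 gave between 218 and 409. The test thus stayed under 514 in every grouping, and 327 lay within the range of the other splits. Limma voom called 0 genes with and without quality weights. DESeq2 called 130 in all (73 higher and 57 lower), and edgeR without a filter 52 (29 higher and 23 lower). In 1106 genes, 10.8% of those tested, the libraries of the groups did not overlap, and chance gives 10% for 3 against 3. Libraries of one group were as far apart as libraries of different groups (mean Spearman correlation over genes 0.669 within and 0.668 between groups). The biological coefficient of variation was 1.42.

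Genes of inflammatory signalling and NF-kB were mostly higher in MTZ, 22 of 28 tested members, with a median log2 fold change of 0.76. The transcription factor gene cebpb had 1132 ± 283 CPM in MTZ and 535 ± 38.2 in DMSO. The cytokine-feedback inhibitor gene socs3a had 521 ± 89.2 against 233 ± 60.7, and the NF-kB inhibitor gene nfkbiab had 651 ± 239 against 377 ± 50.7. The list did not pass (camera adjusted p = 0.0671, or 0.671 with an estimated correlation). No member passed over all genes or when adjusted over the list alone (smallest adjusted p 0.0512). In the list of heat shock and immediate early genes, 20 of 39 members were higher and 19 lower, and the list did not pass (camera adjusted p = 0.215). Adjusted over the list alone, 3 of its members passed and were higher in MTZ: junbb, socs3a and the MAP kinase phosphatase gene dusp2, with a mean of 521 CPM against 181 CPM (log2 fold change 1.53 ± 0.33). Adjusted over all genes, 0 passed, and an adjustment over the list alone makes no allowance for the other lists tried.

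Ribosomal protein genes fell slightly as a group in MTZ (camera adjusted p = 0.0359), the only call among the 33 lists tested. The call was lost when the correlation was estimated, at 0.265 (adjusted p = 0.862 with an estimated correlation). Of 82 tested members 70 were lower, with a median log2 fold change of -0.16, which lay between -0.15 and -0.18 under the 5 scalings of the libraries tried. Summed over the list, the DMSO libraries had 109020, 83371 and 95730 CPM and the MTZ libraries 85892, 89976 and 92632 CPM (exact permutation p = 0.5), so DMSO 2 lay below every MTZ library. The members of smallest p were rpl31 (ENSDARG00000053365) with 231 ± 42.5 CPM in MTZ and 371 ± 34.1 in DMSO and rpl11 (ENSDARG00000043509) with 578 ± 69.3 against 820 ± 38.7. They were followed by rpl8 (ENSDARG00000014867) with 793 ± 63.6 against 1081 ± 130 and rplp0 (ENSDARG00000051783) with 1526 ± 241 against 2070 ± 381. No member passed over all genes or when adjusted over the list alone. The list's adjusted p was 0.191 without DMSO 1, 0.157 without DMSO 3, 0.0944 without MTZ 1, 0.178 without MTZ 3, 0.490 with fry and 0.0934 without a filter. Its values lay in a range from 0.000572 to 0.862 over 13 alternatives. Nuclear genes of oxidative phosphorylation had 66 of 100 members lower, with a median of -0.21, and did not pass (camera adjusted p = 0.0980). Among them, the complex I gene ndufv1 had 165 ± 42.9 CPM in MTZ and 309 ± 31.3 in DMSO, and the ATP synthase gene atp5fa1 had 226 ± 50.1 against 393 ± 105.

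T cell genes were lower in MTZ in 10 of 11 tested members (median log2 fold change -0.78), without passing the list test (camera adjusted p = 0.0792, or 0.671 with an estimated correlation). The transcription factor genes gata3 and tox had 73.7 ± 70.33 and 5.26 ± 6.05 CPM in MTZ against 235 ± 133 and 52.5 ± 60.3 in DMSO, where tox had 122 CPM in DMSO 1 and 18.5 and 16.8 CPM in the others. With a library left out, the log2 fold change ran from -2.58 to -1.09 for gata3 and from -4.74 to -1.74 for tox. The co-stimulatory receptor gene cd28 was the member on the other side, with 59.9 ± 23.0 CPM in MTZ and 15.4 ± 6.69 in DMSO. T cell markers summed to 897, 1041 and 1192 CPM in the DMSO libraries and to 301, 820 and 635 CPM in the MTZ libraries. In MTZ 1, the lowest of these, lck had 0.0540 and gata3 2.43 CPM, and neutrophil markers summed to 16709 CPM against 1336 and 2472 in the other MTZ libraries. Without MTZ 1 the T cell list had an adjusted p of 0.228. It passed without a filter (0.0343) and with a filter of 10 CPM in 3 libraries (0.0409). Lymphoid progenitor genes were split, 6 higher and 8 lower (median -0.05, camera adjusted p = 0.215). Stem and progenitor genes had 8 of 11 members higher (median log2 fold change 0.51, mean 0.19, camera adjusted p = 0.132). The ETS factor gene fli1a, with 442 ± 201 CPM in MTZ and 98.7 ± 50.9 in DMSO, was the member that passed when adjusted over the list alone. The progenitor gene lmo2 had 226 ± 85.7 against 132 ± 84.0, with a log2 fold change from 0.45 to 1.43 with a library left out. The lower member zfpm1 had 4.61 ± 6.97 CPM in MTZ and 46.65 ± 54.7 in DMSO.

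Thrombocyte genes had 7 of 10 members higher in MTZ (median 0.77, camera adjusted p = 0.0838). The integrin gene itga2b, with 63.1 ± 13.2 CPM in MTZ and 0.685 ± 1.02 in DMSO, and the clotting factor gene f13a1b, with 146 ± 21.9 against 30.2 ± 16.98, passed when adjusted over the list alone. Without DMSO 1, which had 1.87 CPM against 0.0585 and 0.132 in the other DMSO libraries, the log2 fold change of itga2b moved from 6.52 to 9.29. The lower member fn1b had 6.88 ± 5.41 CPM in MTZ and 48.2 ± 78.45 in DMSO, where DMSO 3 had 138.7 CPM. No member of the thrombocyte list passed over all genes. Of 22 skin epithelium genes found, 5 were tested, and all 5 were higher (median 0.98, camera adjusted p = 0.0792). Without a filter the list had 14 members and turned lower (adjusted p = 0.793), and with a filter of 10 CPM in 3 libraries it passed as higher (0.0409). Its markers summed to 414 ± 156 CPM in MTZ and 367 ± 364 in DMSO (exact permutation p = 0.8), with the highest sum, 787 CPM, in DMSO 1. Among the tested members were cldni, a claudin, with 77.9 ± 68.7 against 8.97 ± 10.9 CPM (log2 fold change from 2.21 to 4.87 with a library left out) and the keratin gene krt8 with 160.1 ± 36.06 against 81.3 ± 34.9. The liver list had 4 tested members, of which 3 were higher (median 0.68, camera adjusted p = 0.140), and its rbp4 passed when adjusted over the list alone. Directional fry called the liver list (adjusted p = 0.00160), and without a filter it had 9 members and turned lower (adjusted p = 0.930). Its markers summed to a mean of 493 CPM in MTZ, of which rbp4 alone had 473 CPM. The other tested members, cfh and the hp genes, had edgeR unadjusted p-values between 0.534 and 0.953. The fry call therefore does not show that liver genes were higher as a group. B cell genes had 3 of 4 members higher (median 0.96, camera adjusted p = 0.222).

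**Figure D2:**
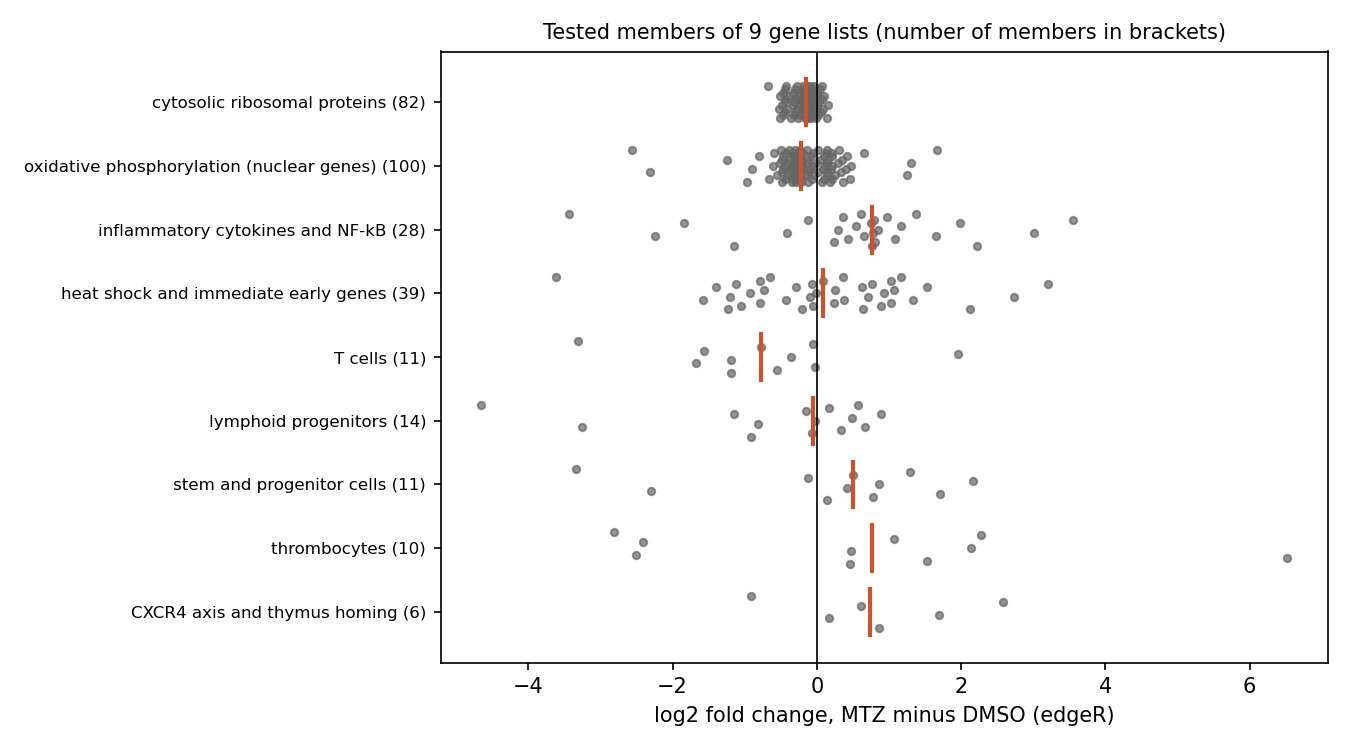
Log2 fold changes of the tested members of 9 gene lists, MTZ minus DMSO, 1 grey point per gene, with the number of members in brackets, a vertical orange line at each median and a black line at 0. Ribosomal protein genes lie in a narrow band with a median of -0.16, and T cell genes lie below 0 in 10 of 11 cases.

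Without DMSO 1, the inflammatory list, the stem and progenitor list (both higher) and the oxidative phosphorylation list (lower) passed, each with a camera adjusted p of 0.0106. Their ranges over 13 alternatives ran from 0.000587 to 0.671, from 0.0106 to 0.862 and from 0.0106 to 0.862. The inflammatory list also passed without DMSO 2, MTZ 1 or MTZ 2 (0.000587, 0.0275 and 0.0114) and without a filter on low counts (0.00230). The T cell and thrombocyte lists passed without MTZ 2 (0.0147 and 0.0498, in ranges from 0.0147 and 0.0127 to 0.671), and so did the oxidative phosphorylation list (0.0157). With a filter of 10 CPM in 3 libraries 4 cell type and 3 pathway lists passed, and 0 of the 33 lists passed with an estimated correlation. DESeq2 called the list members cebpb, socs3a, dusp2, fli1a, itga2b and f13a1b, all higher in MTZ, with adjusted p-values from 0.000250 to 0.0424. EdgeR without a filter called cebpb, dusp2 and fli1a. Other list members called by DESeq2 included tfr1a (erythroid list), with no counts in MTZ, and cd74a (antigen presentation list). Both were lower in MTZ (DESeq2 adjusted p = 0.01045 and 0.0459).

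Markers of other cell types differed widely between single libraries of both groups. Skeletal muscle transcripts summed to 10457 CPM in DMSO 1 and to between 2.105 and 84.1 CPM in the other libraries, led by the actin gene actc1b with 5340 CPM. The keratin genes krt4 and krt5 had 102 and 84.5 CPM there and at most 0.108 and 0.0619 CPM elsewhere. Pancreatic enzyme transcripts summed to 827 CPM in MTZ 3 and to at most 92.6 CPM elsewhere. The lysozyme gene lyz of neutrophils had 3453, 4.44 and 3183 CPM in the DMSO libraries and 9301, 6.68 and 5.31 CPM in the MTZ libraries. Neutrophil markers summed to between 2087 and 5974 CPM in DMSO and between 1336 and 16709 CPM in MTZ (exact permutation p = 0.9). Markers of NK and innate lymphoid cells summed to between 263 and 973 CPM and between 169 and 1023 CPM (exact permutation p = 0.8). In 20 of the 40 lists the sum differed more than 2-fold within a group.

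**Figure D3:**
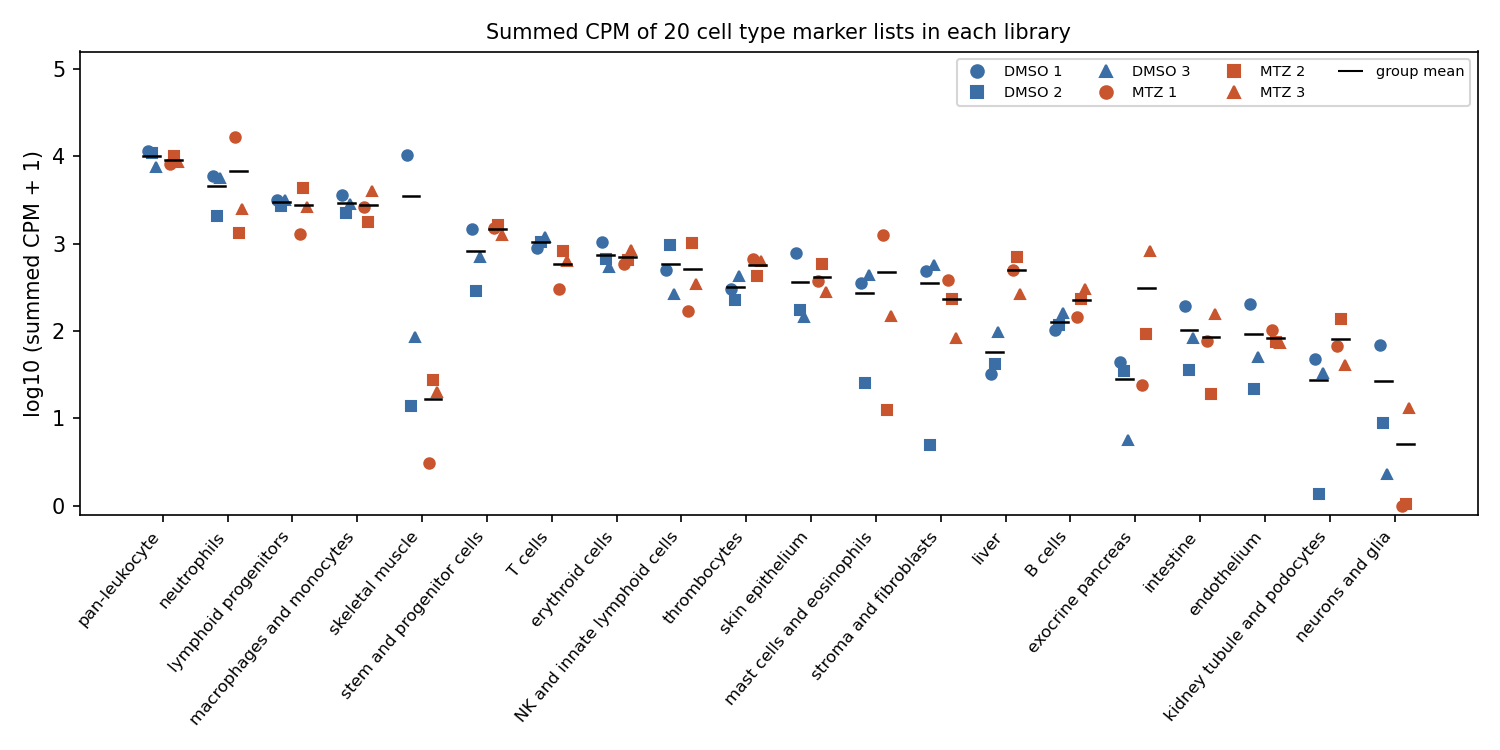
Summed CPM of 20 cell type marker lists in each library, as log10 of the sum plus 1, for the 3 DMSO (blue) and 3 MTZ (orange) libraries, with a bar at the mean of each group. Skeletal muscle markers stand at 10457 CPM in DMSO 1 and at no more than 84.1 CPM in the other libraries.

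The remaining blood cell lists did not pass. Neutrophil genes had 13 of 18 members higher (camera adjusted p = 0.663), macrophage and monocyte genes 9 of 20 (0.547), NK and innate lymphoid genes 5 of 9 (0.418), erythroid genes 5 of 11 (0.942) and pan-leukocyte genes 5 of 12 (0.852). The remaining pathway lists (cell cycle, histones, actin and adhesion, interferon, unfolded protein, oxidative stress, p53, lysosome, glycolysis, antigen presentation, translation, mitochondrial transcripts, other chemokines and Notch, Wnt and cytokine signalling) had camera adjusted p-values between 0.301 and 0.942. In the actin and adhesion list, the GTPase gene cdc42 had 485 ± 62.0 CPM in MTZ and 214 ± 33.99 in DMSO. The actin-severing cofilin gene cfl1 had 651 ± 59.3 against 1032 ± 275. Neither passed over all genes in edgeR or when adjusted over the list alone, and DESeq2 called cdc42 (adjusted p = 0.00501). In 9 lists the median, mean and test differed in sign, namely neutrophils, NK and innate lymphoid cells, macrophages, erythroid cells, mitosis, glycolysis, antigen presentation, other chemokines, and Notch, Wnt and cytokine signalling. The stroma list (4 of 10 members higher) also did not pass (camera adjusted p = 0.663), and 7 lists had too few tested members. Of these 7, the skeletal muscle list passed as lower in all 6 alternatives that tested it (adjusted p from 2.61e-08 to 0.0318), and without DMSO 1 it was not tested. The exocrine pancreas list passed as higher without a filter (0.0218) and without MTZ 1 (0.0109), 2 of the 6 alternatives that tested it. Single libraries decided some of these results: neutrophil genes passed as lower without MTZ 1 (camera adjusted p = 0.00952, in a range from 0.00952 to 0.967 over 13 alternatives). Lymphoid progenitor, NK and mitosis genes passed as lower without MTZ 2 (0.0228, 0.0243 and 0.0442, with highest values of 0.935, 0.954 and 0.990). Stroma genes passed as lower without DMSO 2 (0.00206, with a highest value of 0.990).

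In the numbers of genes and the shares of the main transcript classes, the libraries of the groups overlapped. The permutation tests below cannot show that the groups were alike, because they cannot give a p below 0.1. Genes with a count of at least 1 numbered 11559 ± 306 in DMSO and 11940 ± 621 in MTZ (exact permutation p = 0.6). Those with a count of at least 10 numbered 9639 ± 41.2 and 9974 ± 814 (exact permutation p = 0.7). Mitochondrial genome transcripts took 4.47 ± 0.140% and 4.26 ± 0.355% of the counts (exact permutation p = 0.5), and ribosomal protein genes took 9.48 ± 0.686% and 8.72 ± 0.262% (exact permutation p = 0.2). Hemoglobin genes took 0.0426 ± 0.0102% and 0.0400 ± 0.00472% (exact permutation p = 0.8), and the 10 most abundant genes 11.5 ± 2.43% and 10.6 ± 0.622% (exact permutation p = 0.9). Total counts were higher in all 3 MTZ libraries, at 18737882 ± 1875904 against 15122996 ± 1185538 (exact permutation p = 0.1, the smallest that 3 against 3 can give). The difference in genes with at least 1 count was 382, and it came to 189 with counts thinned to 1 total and to 27.3 without MTZ 3. The difference in the mitochondrial share moved from -0.208 to -0.00336 percentage points without MTZ 1, and that in the ribosomal protein share from -0.755 to -1.147 without DMSO 2. Without MTZ 3 the difference in genes with at least 10 counts turned to -87, and without DMSO 1 the differences in the 10 most abundant genes and in hemoglobin turned to 0.512 and 0.00153 percentage points.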

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

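The gene count stayed at 0 in 16 of 18 alternatives, with every scaling, with either voom fit and without any 1 library, while DESeq2 called 130 genes and edgeR without a filter 52. The cause was not tested for the unfiltered run; DESeq2 is weighed among the other observations. Cell type lists passing numbered 0 in the planned test, 1 with directional fry (liver) and 3 without a filter. They numbered 4 with 10 CPM in 3 libraries and 1 to 5 with a library left out. Lists too small for the planned test are counted too where they reached 3 tested members, so the rise from 0 is partly theirs. Skeletal muscle, at 10457 CPM in DMSO 1, passed in all 6 alternatives that tested it. Exocrine pancreas passed without a filter and without MTZ 1. Pathway lists passing numbered 1 in the planned test, 0 with an estimated correlation, 0 with directional or mixed fry, 1 without a filter (inflammatory, not ribosomal protein), 3 with 10 CPM in 3 libraries, and 0 to 4 with a library left out. The libraries share only a number between groups: same-numbered deviations correlated at -0.00794, -0.000827 and -0.0459. With the number as a replicate block 0 genes, 0 cell type lists and 0 pathway lists passed, so the ribosomal protein call was not made (adjusted p 0.0569), and no other call changed. Without a filter 6 lists turned direction, none passing: skin (adjusted p 0.793), liver (0.930), erythroid (0.558), and other chemokines, antigen presentation and lysosome (0.937 each). Mitosis turned with fry, stroma with the block, Notch, Wnt and cytokine signalling with 10 CPM in 3 libraries, and 12 lists with a library left out, 0 of them passing. Of 60 genes followed, 50 kept their direction in every alternative run. In log2 fold change, voom turned icn to -0.16, fn1b to 0.20, hp (ENSDARG00000095807) to -0.0368 and cd22 to 2.38. Voom with quality weights turned ccr9a to -0.0376, fn1b to 0.0725, that hp to -0.13 and cd22 to 2.78. The replicate block turned icn to -0.65, fn1b to 0.79 and cd22 to 3.15. With a library left out, the values ran from -0.33 to 0.54 for ccr9a, -0.27 to 0.77 for myb, -1.23 to 0.48 for runx1, -1.112 to 1.295 for icn and -3.38 to 1.23 for fn1b. They ran from -3.04 to 0.38 and from -0.76 to 0.76 for the 2 hp genes (ENSDARG00000051890 and ENSDARG00000095807), -1.004 to 10.56 for cfh, -3.83 to 10.51 for cd22 and -1.18 to 7.71 for ccl25b. In composition, the differences with a library left out ran from -87 to 724.5 for genes with 10 counts, from -1.68 to 0.512 percentage points for the 10 most abundant genes and from -0.00822 to 0.00153 for hemoglobin. Causes of these changes were not tested. Of 1072 comparisons of a followed gene with an alternative, 1023 kept direction and stayed uncalled, 24 gained a call (15 with DESeq2) and 25 turned direction. The planned test called 0 genes, so no followed gene had a call to lose. Many of them were chosen for a small p, which favours a stable direction. At the real dispersion and depth, simulated 4-fold changes were recovered in 4 of 57 tested genes and 64-fold changes in 34 of 61.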

Other observations

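The tests on muscle transcripts and the simulated counts with nothing changed were chosen after the results were seen, and the counts over other splits before.

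The macrophage gene mfap4 differed between libraries of both groups, with 124, 85.1 and 330 CPM in DMSO and 468, 1.55 and 1520 CPM in MTZ. The peptidase gene cpa5, a mast cell marker, had 346, 0.468 and 442 CPM in DMSO and 1198, 1.05 and 134 CPM in MTZ. In both DMSO 2 and MTZ 2, lyz and cpa5 were low, while nkl.4, an NK-lysin gene, was at its highest, with 65.9 and 211 CPM. In MTZ 3, lyz was as low (5.31 CPM), but nkl.4 had 3.03 CPM. The innate lymphoid cytokine gene il13 had 471 CPM in DMSO 2 and at most 29.3 CPM in any other library. Digestive enzyme genes prss1, ela2l, ela2 and ctrb1 had 108, 104, 91.5 and 85.7 CPM in MTZ 3 and at most 10.5 CPM elsewhere.

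The first pattern was the gap between DESeq2, with 130 genes, and edgeR, with 0. Of the 130 genes, 85 (65.4%) had at most 3 counts in every library of 1 group, close to the 67.5% among the DESeq2 calls of the other splits. Transcripts caught in some pools of few cells and missed in others would give as many calls in groups that mix the treatments. The 9 other splits of the 6 libraries into 3 and 3 gave a mean of 137.2 DESeq2 calls, with a highest of 181. Those splits mix the treatments unevenly, so part of a treatment effect would remain in them. In simulated counts at the real dispersion with nothing changed, DESeq2 called 106 genes and edgeR 0. That simulation had no step that drops transcripts, so it shows only that this dispersion can give many DESeq2 calls. It does not show that missed transcripts were the cause. The treatment stays open for single genes: the splits (7 of 10 gave at least 130 calls by DESeq2) are too few for a share under 0.05, and the edgeR count over splits says nothing, since 10 of 10 reach a real count of 0 (highest other 2).

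The second pattern was the lower ribosomal protein list in MTZ. Members that move together between libraries, whatever the treatment, may produce such a call, and 2 of the 9 other splits also called this list, with adjusted p-values of 0.00353 and 0.0343 against 0.0359 for the real one. Both of those splits keep DMSO 1 and DMSO 3 together, and the other split that does so, with MTZ 1, had 0.0733. Each side of these splits holds 2 libraries of 1 treatment and 1 of the other, so part of a treatment effect would remain. The splits therefore cannot tell members moving together from the treatment. The correlation between members that camera estimated with the group in the model was 0.265, against the preset of 0.01. With this estimate the camera adjusted p of the real split was 0.862. The members thus moved together within the groups, and the call rests on the preset correlation. All 10 splits called at least 1 list, 1 for the real split and 8 for the highest of the others, and 10 splits are too few for a share under 0.05. An effect of the treatment on these genes stays open and untested.

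The third pattern was the skeletal muscle transcripts of DMSO 1. Of 20 muscle markers with at least 10 CPM in any library, 100% were highest in DMSO 1, with actc1b at 5340, pvalb2 at 886 and mylpfa at 638 CPM. This restates the pattern that prompted it, so it does not decide whether muscle cells or their RNA were in that pool. Reads shared between copies of 1 gene family are argued against, because the 14 markers over 100 CPM there came from 6 families by the first 3 letters of their symbols. The source of these transcripts stays open, and no biological explanation was tested.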
